A study of Mus musculus with 18 samples.

How the data were processed

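The series holds RNA sequencing of whole spinal cord from 18 mice aged 10 months, 3 animals in each of 6 genotypes, and 1 table of gene counts for all of them. Per the labels' protocols, RNA was extracted with QIAzol and a miRNeasy kit with DNase treatment on the column, all extractions had an RNA integrity number above 7.5, ribosomal RNA was depleted, libraries were made with the stranded SMARTer total RNA kit from Takara, and read pairs of 100 bases were sequenced on 3 lanes of a HiSeq4000. Trim Galore 0.4.1, TopHat2, featureCounts, DESeq2 and the mm10 genome are named, without role or order, in the submitters' processing notes. Whole-number read counts per gene were made with featureCounts in stranded paired mode on exons of the GENCODE mouse annotation, per the file headers, which also give each gene's summed exon length and the TopHat alignment of each animal. Those settings count each read pair for 1 gene only, and leave out pairs that match several genes or several places in the genome, so genes with near-identical copies are undercounted. The strand setting keeps antisense genes apart. Sex, litter, and the allotment of animals to extraction days or lanes were not given in the sources used here, and reads of the human sequences were not analysed here.

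Each count column was tied to its sample by the animal number in the column name and the sample title. Gene symbols were matched through a separate table for 54409 of 54446 gene identifiers (99.93%). Coordinates are those of mm10 as the count table gives them, from the first exon start to the last exon end of a gene. Replicate numbers follow the order of the accessions and only name a library.

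Depth ran from 16061359 to 30978678 counts per library. CPM values are counts divided by the library total times its TMM factor (0.861 to 1.109) and scaled to a common size. The floor is given as 3 counts of a library total and, like any interval from counts alone, covers counting error only, while SDs and SEs describe the spread between animals. Reads without molecular identifiers are not independent molecules. On data simulated from the real gene means, library sizes and spread, the edgeR test of the Q33 double knock-in against NTg recovered 37.5% of 80 genes changed 1.5-fold, 76.2% of 80 changed 2-fold and nearly all of 40 changed 4-fold, with 5 false calls among 20267 genes. For the interaction with the Q33 tract it recovered 6.25% of 80 genes changed 1.5-fold, 56.2% of 80 changed 2-fold and 87.5% of 40 changed 4-fold, with 3 false calls among 20277 genes. The changed genes were drawn only from genes with a mean of at least 1 CPM, so these shares do not cover genes below that level. A 1.5-fold shift of every gene of the interferon list was found by the list test in each of the 11 planned comparisons, with at most 1 of the other lists called. The simulated genes were drawn independently of each other. These counts therefore do not show how often the list test calls lists falsely where genes move together, as they can in real cords.

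The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on the deposited counts, two-sided, with TMM scaling and edgeR's filter for low counts, which kept 20635 genes. All 18 libraries entered 1 fit with a term for each genotype, because groups of 3 estimate the spread poorly alone, and p-values were adjusted by the Benjamini-Hochberg method within each comparison at a threshold of 0.05. There were 9 planned comparisons of 2 groups and 2 planned interactions of an ATXN2 form with TDP-43. A comparison of the Q33 double knock-in with Q33, and a contrast of the tract length difference with and without TDP-43, were added after the data were seen. Log2 fold changes are edgeR estimates with SEs derived from the test, and log2 CPM values use a prior count of 2.

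Genes were grouped in 39 lists of cell type markers and pathways. As sets, 36 were tested with camera at a preset correlation of 0.01 between genes, and 3 (strain markers, sex-linked genes and the targeted genes) were read gene by gene. Camera was repeated with an estimated correlation, and fry tested whether the genes of a list moved one way. Counts of list members that changed are given over all genes tested and adjusted over the list alone. The lists, the main design, the other methods named below as chosen in advance and the rule for naming genes were chosen before the data were examined.

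That rule took, for each comparison of 2 groups, Atxn2 and Tardbp; the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 1 CPM in either group and no overlap between the libraries; the 3 members with the smallest adjusted p of each list that passed camera or had 2 or more called members; and, where fewer than 5 genes qualified by size, the 5 with the smallest p. Gene models without a known role could stay unnamed, and sex-linked genes were read only for the sex balance. Some genes that the rule takes are not reported here. Genes named outside the rule are marked as chosen after their values were seen.

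The other methods chosen in advance were DESeq2 1.42.0, limma-voom with sample weights, median-of-ratios scaling, no filter, a filter of 1 CPM in 3 libraries, only the groups compared in the fit, sex as a covariate, and each library left out in turn. Covariates for the share of mitochondrial ribosomal RNA and for the mean of the Hox10 and Hox11 genes, scaling by library totals, and a fit without mitochondrial genes were added after the data were seen. Under library totals the median log2 fold change of all genes was -0.253, -0.246 and -0.249 when the Q33 double knock-in was compared with NTg, the Q22 double knock-in and TDP-43 (with TMM -0.012, -0.014 and -0.021), -0.15 against Q33 (-0.011), -0.221 in the tract length contrast (-0.004), -0.101 for Q33 against NTg (0) and -0.151 in the Q33 interaction (-0.024), so changes are relative to the scaling used. Comparisons that share libraries were set beside 5 simulated data sets in which no gene differed.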

Results

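Total RNA was sequenced from the whole spinal cord of 18 untreated mice aged 10 months, 3 from each of 6 genotypes. Non-transgenic C57BL/6 mice (NTg) were the controls. The other 5 groups were heterozygous for human sequences knocked in: ATXN2 with a tract of 22 glutamines (Q22), ATXN2 with 33 glutamines (Q33), TDP-43, or TDP-43 together with either form of ATXN2 (the Q22 and Q33 double knock-ins). ATXN2 is an RNA-binding protein whose glutamine tract, when moderately expanded, is a known risk factor for amyotrophic lateral sclerosis (ALS). TDP-43 is the RNA-binding protein that forms inclusions in most patients with that disease. Gene counts summed to between 16061359 and 30978678 per library, with a median of 23807573.5, and between 27050 and 29074 genes had at least 1 count. At these depths 3 counts corresponded to between 0.097 and 0.19 CPM (counts scaled to a common library size). Each library came from its own animal and counted as 1 sample.

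Several library properties moved with the genotype. Mitochondrial ribosomal RNA held 26.1% ± 2.65 of the counts in the Q33 double knock-in (SD, n = 3) against 17.8% ± 3.02 in NTg, 20.1% ± 0.551 in Q22, 20.4% ± 2.67 in Q33, 17.7% ± 4.39 in TDP-43 and 18.7% ± 1.78 in the Q22 double knock-in. The 3 libraries of the Q33 double knock-in had 28.7%, 26.3% and 23.4%, and the other 15 lay between 12.7% and 23.4%. The mean log2 CPM of the Hox10 and Hox11 genes, which mark the lumbar and sacral levels of the cord, was 1.62 ± 1.52 in the Q33 double knock-in, 0.71 ± 2.78 in Q33, -0.09 ± 3.15 in the Q22 double knock-in and -1.39 ± 0.628 in NTg. It was -1.37 ± 1.02 in Q22 and -1.75 ± 0.463 in TDP-43. Reads of 4 Y-linked genes together exceeded 10 CPM in 0 of 3 NTg libraries, 3 of 3 Q22 libraries, 2 of 3 Q33 libraries, 2 of 3 TDP-43 libraries and 1 of 3 libraries of each double knock-in. Sex was therefore not balanced, and in the comparison of Q22 with NTg it coincided with the genotype.

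**Figure D1:**
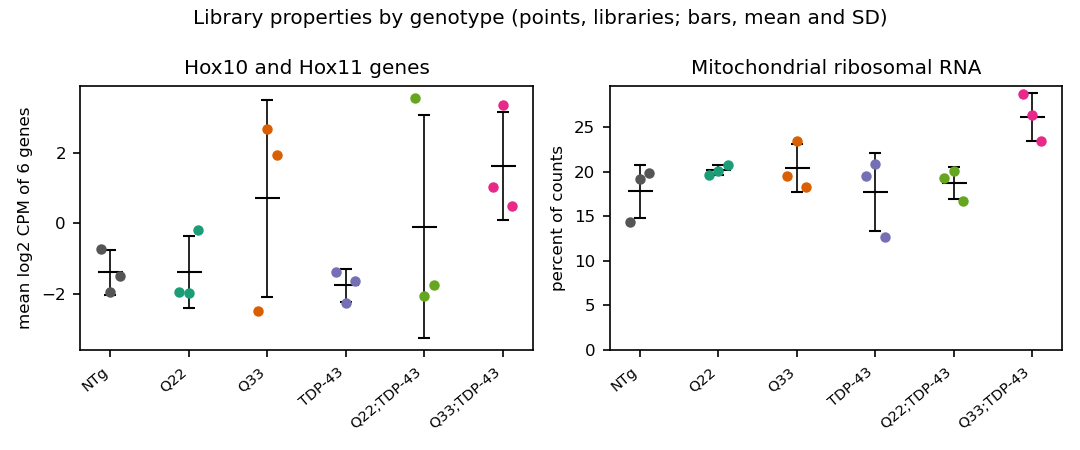
Library properties by genotype, with points for libraries and bars for the mean and SD of 3 libraries. The left panel gives the mean log2 CPM of Hox10 and Hox11 genes and the right panel the percent of counts on mitochondrial ribosomal RNA, which was 28.7, 26.3 and 23.4 in the libraries of the Q33 double knock-in.

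The mouse genes that correspond to the human knock-ins were read first. Atxn2 (ENSMUSG00000042605.16, chromosome 5, 121711337 to 121816493 of mm10) was measured at 182 ± 12.6 CPM in NTg, 182 ± 5.56 in Q22, 180 ± 8.29 in Q33, 181 ± 10.7 in TDP-43, 177 ± 8.49 in the Q22 double knock-in and 185 ± 15 in the Q33 double knock-in (SD, n = 3). Tardbp, which encodes mouse TDP-43 (ENSMUSG00000041459.15, chromosome 4, 148612382 to 148627019), had 126 ± 2.21, 109 ± 1.71, 119 ± 3.26, 121 ± 2.7, 121 ± 9.07 and 122 ± 4.88 CPM in the same order. Neither gene passed the edgeR test in a comparison with NTg. The lowest Tardbp estimate was a log2 fold change of -0.21 (SE 0.07, adjusted p = 0.91) in Q22. Reads were counted on mouse genes only, so these values neither check nor measure the human sequences.

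The Q33 double knock-in was compared with NTg to ask what the longer tract and human TDP-43 together changed. Its cords had lower levels of dorsal horn neuron genes: Lmx1b, a transcription factor of dorsal excitatory interneurons, fell from 20.1 ± 1.48 to 3.41 ± 2.32 CPM, and the tachykinin gene Tac2 from 14.7 ± 3.7 to 1.84 ± 2.14 CPM (SD, n = 3). The complement genes C3 (161 ± 65 to 17.7 ± 13 CPM) and C4b (98.4 ± 18.5 to 18.7 ± 8.58 CPM) fell, as did the apelin receptor gene Aplnr (10.9 ± 4.29 to 0.376 ± 0.233 CPM). Snap25, which encodes a component of the synaptic fusion machinery, rose from 3150 ± 397 to 4850 ± 780 CPM, and the ribosomal protein gene Rpsa from 202 ± 21.3 to 334 ± 70.2 CPM. In all, 1173 genes rose and 1318 fell among the 20635 tested (edgeR quasi-likelihood test, adjusted p under 0.05), of which 52 and 511 changed at least 2-fold, and 5852 genes had an unadjusted p under 0.05 against 1032 by chance.

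**Figure D2:**
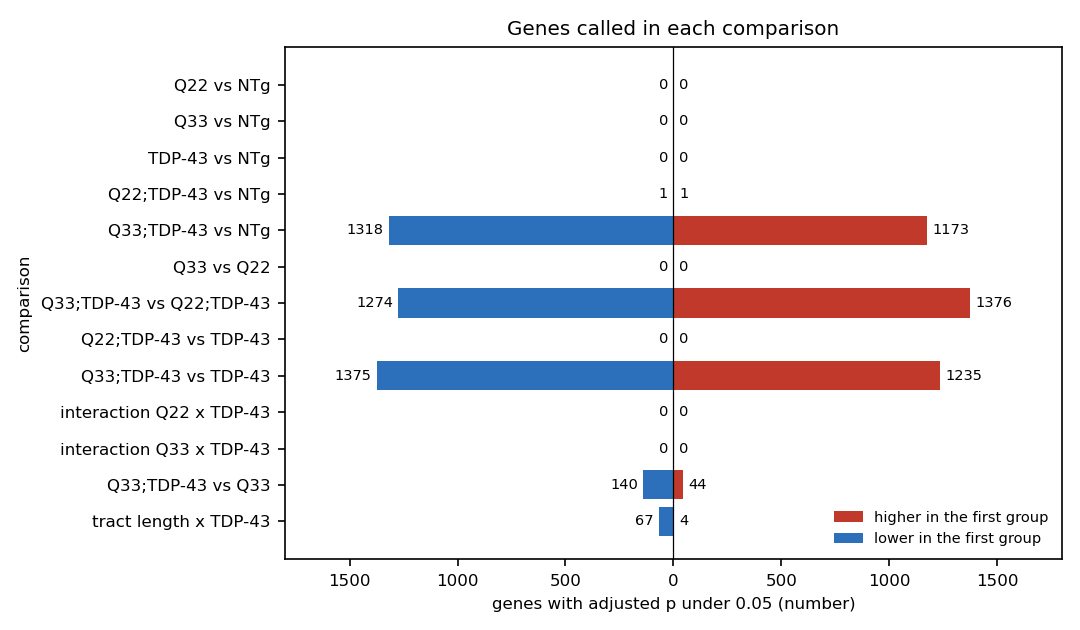
Number of genes with an edgeR adjusted p under 0.05 in each comparison, with genes higher in the first-named group to the right and lower ones to the left of 0. The Q33 double knock-in (Q33;TDP-43) differed from NTg in 1173 and 1318 genes, from the Q22 double knock-in in 1376 and 1274, and from TDP-43 in 1235 and 1375, while each single knock-in had 0 against NTg.

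Of the 2491 called genes, 2393 had a mean of at least 1 CPM in either group. Of these, 1137 were higher and 1213 lower in the Q33 double knock-in with no overlap between the libraries of the groups. Among unchanged genes 10% would not overlap by chance, but the called genes were selected for their difference, so that rate is no yardstick for these counts. The 10 largest falls included Aplnr (log2 fold change -4.84, SE 0.58, edgeR adjusted p = 0.00012), the carbonic anhydrase gene Car12 (-4.18, SE 0.41, 4.2e-05), Myoc (-4.49, SE 0.61, 0.00028) and the transcription factor gene Ebf2 (-3.65, SE 0.43, 1e-04). Nmu, which encodes neuromedin U, fell by 3.42 on the log2 scale (SE 0.7, edgeR adjusted p = 0.0059), and its receptor gene Nmur2 by 3.81 (SE 0.61, 0.001). Ccdc172 (-5.14), Catsperg1 (-3.46) and C3 (-3.2) completed the named falls. The largest rise was in Hoxd10, from 0.169 ± 0.132 to 11.5 ± 9.41 CPM (log2 fold change 5.98, SE 1.82, edgeR adjusted p = 0.04). Hoxd10 is 1 of the Hox10 and Hox11 genes that mark the lumbar and sacral levels of the cord. Its NTg mean lay near the floor of 3 counts (0.097 to 0.19 CPM). Acta2, the smooth muscle actin gene (1.83, SE 0.34, 0.0034), and the collagen gene Col6a6 (1.91, SE 0.41, 0.0077) rose, as did Adh1 (2.53), Opn4 (2.01) and Olfr558 (1.75). The rule for the largest changes required no overlap between the libraries of the groups, so that separation adds no further support. Hoxd10 lost its call without any 1 NTg library or replicate 1 or 2 of the Q33 double knock-in (adjusted p between 0.089 and 0.13). Olfr558 lost it without any 1 of the 6 libraries (between 0.069 and 0.12), Adh1 without NTg replicate 3 (0.052) and Opn4 without replicate 1 of the Q33 double knock-in (0.057). Car12 lies on chromosome 9 (66713686 to 66766845, ENSMUSG00000032373.15), Aplnr on chromosome 2 (85136225 to 85139923, ENSMUSG00000044338.9) and Ebf2 on chromosome 14 (67233292 to 67430918, ENSMUSG00000022053.13).

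Neuronal genes moved both ways. Of 12 excitatory interneuron and dorsal horn markers, 7 fell and 0 rose (8 fell adjusted over the list alone), among them Lmx1b (log2 fold change -2.57, SE 0.33, edgeR adjusted p = 0.00019; chromosome 2, 33560965 to 33640511, ENSMUSG00000038765.13) and Tac2 (-3.04, SE 0.56, 0.0032). Their median was -1.1 (camera adjusted p = 0.00022, and adjusted p = 0.45 with an estimated correlation). Of 16 motor neuron markers 2 rose, Esrrg (0.67, SE 0.12, 0.0024) and Ret (0.63), and 5 adjusted over the list alone, with a median of 0.67 (camera adjusted p = 0.00061, and adjusted p = 0.59 with an estimated correlation). The higher median of this list was not particular to the double knock-in. It was 0.66 in Q33 against NTg, and 0 when the double knock-in was compared with Q33. The pan-neuronal and neurofilament genes had 7 of 17 higher and 1 lower (9 and 1 adjusted over the list alone, and 4 and 3 under library totals), with Snap25 at 0.62 (SE 0.12, 0.0043), Eno2 at 0.5 and Syt1 at -0.88 (SE 0.16, 0.0023). Their median was 0.5 (camera adjusted p = 0.0035, and adjusted p = 0.5 with an estimated correlation). Synaptic vesicle genes had 9 of 22 higher and 3 lower (11 and 4 adjusted over the list alone, and 4 higher and 6 lower under library totals), with Cplx1 at 0.79. Their median of 0.21 passed camera (adjusted p = 0.024, and adjusted p = 0.59 with an estimated correlation) but turned to -0.04 under library totals. The inhibitory neuron markers had 3 of 10 higher and 2 lower (3 and 4 adjusted over the list alone, median -0.06, camera adjusted p = 0.85): the glycine transporter gene Slc6a5 rose by 0.64 and the somatostatin gene Sst fell by 1.31. Ion channel and glutamate receptor genes had 6 of 22 higher and 6 lower (8 and 7 adjusted over the list alone, median 0.01, or -0.23 under library totals, camera adjusted p = 0.82), with Gria1 at -0.63, Scn2a at -0.81 and Gria3 at 0.5. Ret lost its call without NTg replicate 3 or replicate 1 or 2 of the Q33 double knock-in (edgeR adjusted p = 0.054, 0.055 and 0.06), and Slc6a5 without replicate 1 of the Q33 double knock-in (0.051). Under library totals 0 dorsal horn markers were higher and 7 lower, and 1 motor neuron marker was higher. The inhibitory neuron markers then had 2 higher and 4 lower, and 1 ion channel or receptor gene was higher and 9 lower. The list of motor neuron markers lost its call without replicate 2 of the Q33 double knock-in (mean log2 fold change 0.22 in place of 0.69), and the synaptic list lost it without NTg replicate 3 (mean 0.12 in place of 0.13) or replicate 1 of the Q33 double knock-in (0.09).

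**Figure D3:**
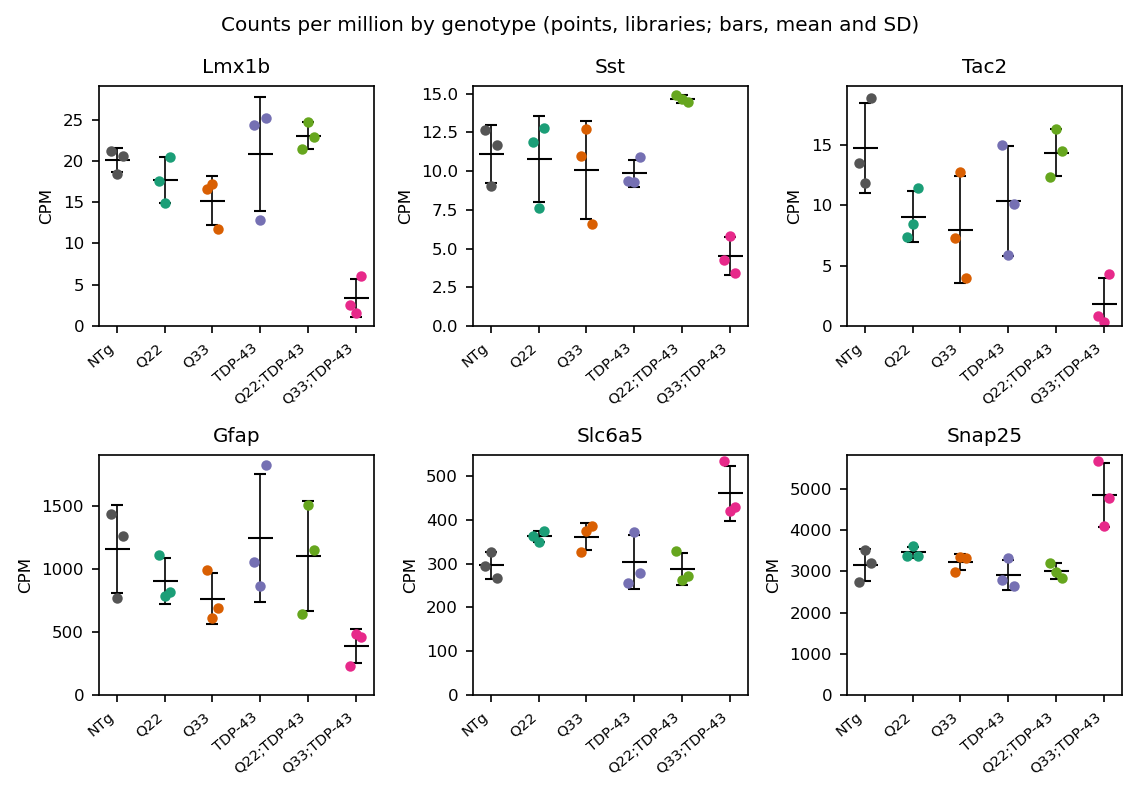
CPM of 6 neural genes by genotype, with points for libraries and bars for the mean and SD of 3 libraries. Lmx1b, Sst, Tac2 and Gfap were lower and Slc6a5 and Snap25 higher in the Q33 double knock-in (3.41, 4.49, 1.84, 390, 461 and 4850 CPM on average).

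Some genes of several glial classes were lower. Of 16 homeostatic microglia markers, 4 fell (5 adjusted over the list alone), with Csf1r at -0.63 (SE 0.13, edgeR adjusted p = 0.0066), and the list median was -0.4 (camera adjusted p = 0.00022, and adjusted p = 0.5 with an estimated correlation). Reactive astrocyte genes had 7 of 18 lower (2 higher and 9 lower adjusted over the list alone), with the hyaluronan receptor gene Cd44 at -2.15 (SE 0.28, 0.00023), Cd109 at -2.78 and C4b at -2.4. Their median was -0.61 (camera adjusted p = 0.0013, and adjusted p = 0.5 with an estimated correlation). The myelin genes had 4 of 19 lower (6 adjusted over the list alone), with Enpp6 at -1.04 and a median of -0.28 (camera adjusted p = 5e-04, and adjusted p = 0.56 with an estimated correlation). Oligodendrocyte precursor markers had 4 of 12 lower (6 adjusted over the list alone), with Cacng4 at -1.01, Pdgfra at -0.42 and a median of -0.24 (camera adjusted p = 0.028, and adjusted p = 0.5 with an estimated correlation). The general astrocyte markers had 1 of 14 higher and 2 lower, including the glutamate transporter gene Slc1a3 at -0.96 (3 and 2 adjusted over the list alone, median -0.02, camera adjusted p = 0.9). Disease-associated microglia genes had 1 of 21 higher (Spp1, at 1.08) and 4 lower, among them Lpl at -1.55 (median -0.28, camera adjusted p = 0.11). Ependymal markers had 1 of 13 lower and a median of -0.77 (camera adjusted p = 0.018, and adjusted p = 0.6 with an estimated correlation). Under library totals more passed as lower: 10 homeostatic microglia markers, 9 reactive astrocyte, 12 myelin, 7 precursor, 5 general astrocyte, 7 disease-associated microglia and 3 ependymal genes, with 1 disease-associated microglia gene higher. Without NTg replicate 1 or replicate 1 of the Q33 double knock-in, the precursor markers (mean log2 fold changes -0.23 and -0.22 in place of -0.29) and the ependymal markers (-0.59 and -0.47 in place of -0.74) lost their calls. Without replicate 1 of the Q33 double knock-in, Csf1r (edgeR adjusted p = 0.052), Pdgfra (0.053) and Spp1 (0.073) lost theirs, and Spp1 also without NTg replicate 1 (0.051) or 3 (0.06). Gfap, the astrocyte filament gene, was chosen after its values were seen: it fell from 1160 ± 346 to 390 ± 136 CPM (log2 fold change -1.57, SE 0.34, edgeR adjusted p = 0.0075).

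Some vascular, energy and translation genes were higher, and fewer of them under library totals. The endothelial markers had 2 of 12 higher (8 adjusted over the list alone) and a median of 0.58 (camera adjusted p = 0.00022, and adjusted p = 0.5 with an estimated correlation). Pericyte and smooth muscle markers had 2 of 9 higher (5 adjusted over the list alone), with Myh11 at 1.24 and a median of 0.58 (camera adjusted p = 0.015, and adjusted p = 0.56 with an estimated correlation). Nuclear oxidative phosphorylation genes had 22 of 35 higher and 0 lower (25 adjusted over the list alone). Uqcrc1 rose by 0.57 and Atp5e from 12.5 ± 0.981 to 20.8 ± 3.95 CPM, and the list median was 0.58, or 0.33 under library totals (camera adjusted p = 7.3e-12, and adjusted p = 0.5 with an estimated correlation). Cytosolic ribosomal protein genes had 15 of 48 higher and 0 lower (27 adjusted over the list alone), with Rpsa at 0.73, Rpl35 at 0.96 and a median of 0.42, or 0.18 under library totals (camera adjusted p = 2e-11, and adjusted p = 0.5 with an estimated correlation). The mitochondrially encoded genes had 1 of 13 higher, mt-Nd6 at 0.34, and a median of 0.4 (camera adjusted p = 0.018, and adjusted p = 0.61 with an estimated correlation). Mitochondrial ribosomal RNA was higher in the same libraries (26.1% against 17.8%). Without NTg replicate 2 or replicate 2 of the Q33 double knock-in the pericyte list lost its call (mean log2 fold changes 0.43 and 0.28 in place of 0.55), and the mitochondrially encoded list lost its call without NTg replicate 3 (mean 0.31 in place of 0.41) or replicate 2 of the Q33 double knock-in (0.12). Under library totals 8 oxidative phosphorylation genes, 3 ribosomal protein genes, 2 pericyte markers, 0 endothelial markers and 0 mitochondrially encoded genes were higher, and 0 of any of these lists lower. The call of mt-Nd6 was lost without NTg replicate 1 or 3 or any 1 library of the Q33 double knock-in (edgeR adjusted p between 0.054 and 0.12).

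Stress and injury genes differed by list. Heat shock genes had 4 of 15 higher (8 adjusted over the list alone), with Hspa8 at 0.52 (SE 0.1, edgeR adjusted p = 0.0045) and a median of 0.39 (camera adjusted p = 0.00046, and adjusted p = 0.56 with an estimated correlation). Axon injury response genes had 7 of 14 lower and 0 higher, with the neuropeptide gene Adcyap1 at -1.18 and Chl1 at -0.5, and a median of -0.53 (camera adjusted p = 0.00081, and adjusted p = 0.5 with an estimated correlation). Unfolded protein response genes had 4 of 22 higher and 1 lower, the serine synthesis gene Phgdh at -0.59. Their median of 0.17 passed camera (adjusted p = 0.03, and adjusted p = 0.61 with an estimated correlation), turned to -0.07 under library totals, and the list lost its call without NTg replicate 2 (mean 0.09 in place of 0.13) or replicate 2 of the Q33 double knock-in (mean 0.08). In the list of ALS genes 3 of 30 were higher and 1 lower (6 and 3 adjusted over the list alone, median 0.05, or -0.19 under library totals, camera adjusted p = 0.35). Tuba4a rose by 0.67 (SE 0.13, edgeR adjusted p = 0.0047). Stress granule and ATXN2 partner genes had 1 of 22 higher and 2 lower (median 0.01, or -0.24 under library totals, camera adjusted p = 0.92). The long neuronal genes known as TDP-43 targets had 2 of 21 higher and 3 lower (median -0.06, camera adjusted p = 0.86), with Nkain2 at -0.67 and Cadps at 0.46. Under library totals 2 ALS genes were higher and 10 lower, 0 stress granule genes higher and 9 lower, and 0 long neuronal genes higher and 8 lower. There were also 0 unfolded protein response genes higher and 3 lower, 1 heat shock gene higher, and 7 axon injury genes lower.

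The remaining lists did not pass camera in this comparison. Their medians were 0.02 for Schwann cell markers (mean -0.17, 1 of 6 lower), -0.6 for dorsal root ganglion markers (1 of 5 lower), 0.29 for fibroblast markers (1 of 14 higher and 2 lower, Col1a2 at -0.96 and Col6a1 at -1.74), -0.41 for erythroid genes (0 of 6) and -0.87 for skeletal muscle genes (1 of 9 higher), for which the mean was -0.38 and the camera direction upward. Medians were also -1.08 for the 1 adipocyte gene tested, 0.01 for 2 lymphocyte genes, -0.05 for interferon response genes (1 of 19 lower), 0.29 for antigen presentation genes (0 of 13), -0.03 for immediate early genes (1 of 17 lower), -0.08 for circadian clock genes (1 of 18 lower, and 7 under library totals) and 0.08 for cholesterol synthesis genes (1 of 23 higher, and under library totals 1 higher, 4 lower and a median of -0.16). Schwann cell and lymphocyte medians also turned, to -0.22 and -0.23, under library totals.

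**Figure D4:**
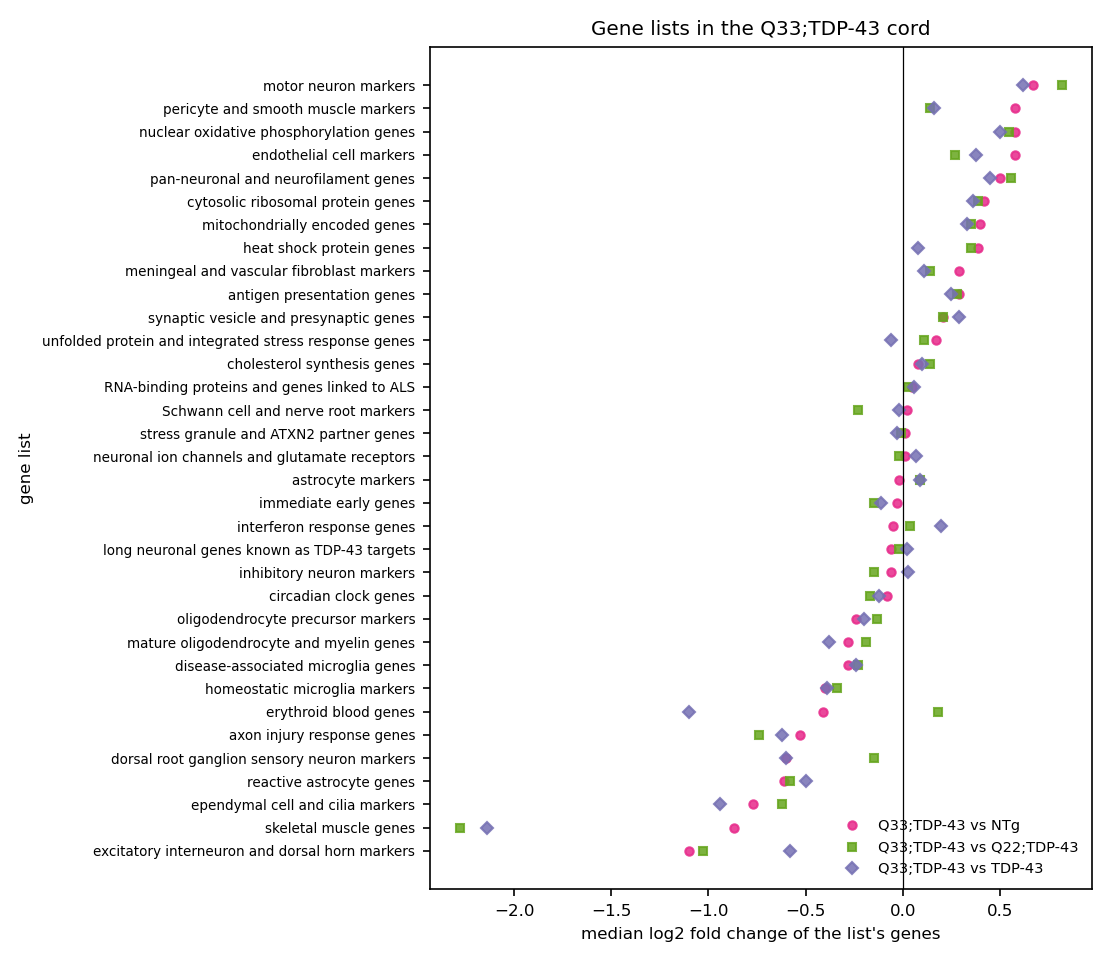
Median log2 fold change of each list with at least 5 tested genes, with circles for the Q33 double knock-in against NTg, squares against the Q22 double knock-in and diamonds against TDP-43. Dorsal horn markers had medians of -1.1, -1.03 and -0.58 and oxidative phosphorylation genes 0.58, 0.55 and 0.5; under library totals the medians in these comparisons are lower, and the synaptic medians of 0.21 against NTg and against the Q22 double knock-in turn to -0.04 and -0.02.

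The count of 2491 genes moved with single libraries: it was 1314 without NTg replicate 1, 993 without NTg replicate 3, 602 without replicate 1 of the Q33 double knock-in and 1559 without its replicate 2. In place of 1173 higher and 1318 lower, DESeq2 called 1777 and 1498, limma-voom 1646 and 1578, and edgeR under library totals 206 and 3940. With the share of mitochondrial ribosomal RNA as a covariate 28 genes passed, and with the Hox score as a covariate 646 did.

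A comparison of both double knock-ins asked what the longer tract changed in the presence of human TDP-43. The Q33 double knock-in again had lower dorsal horn genes: Lmx1b was 3.41 ± 2.32 against 23 ± 1.66 CPM (SD, n = 3). Egr3, an immediate early transcription factor gene, was 0.56 ± 0.163 against 4.16 ± 0.685 CPM. En1, a homeobox gene of ventral inhibitory interneurons, rose by 1.44 on the log2 scale, and Snap25 by 0.69. edgeR called 1376 genes higher and 1274 lower, 59 and 466 of them at least 2-fold.

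The largest falls against the Q22 double knock-in included Gucy2d (log2 fold change -5.18, SE 0.8, edgeR adjusted p = 0.00078), Aplnr (-4.49, SE 0.58, 0.00018), Nmur2 (-4.09, SE 0.6, 0.00051), Car12 (-3.96, SE 0.41, 4.1e-05), Ebf2 (-3.63, SE 0.43, 8.1e-05) and the relaxin-3 receptor gene Rxfp3 (-3.56, SE 0.48, 0.00027), each with no overlap between the libraries, as the rule required. Of the dorsal horn markers 7 of 12 fell and 0 rose, with Lmx1b at -2.77 and Tac1 at -1.39 (median -1.03, camera adjusted p = 0.00016, and adjusted p = 0.25 with an estimated correlation). Motor neuron markers had 4 of 16 higher, with Esrrg at 0.83 and Ret at 0.77 (median 0.82, camera adjusted p = 5.4e-05, and adjusted p = 0.65 with an estimated correlation). Pan-neuronal genes had 7 of 17 higher and 2 lower, with Elavl4 at 0.67 and Syt1 at -1 (median 0.56, camera adjusted p = 0.016, and adjusted p = 0.65 with an estimated correlation). Axon injury genes had 7 of 14 lower (median -0.74, camera adjusted p = 0.00013, and adjusted p = 0.31 with an estimated correlation), and reactive astrocyte genes 7 of 18 lower and 1 higher, with Cd44 at -2.1 and C4b at -2.27 (median -0.58, camera adjusted p = 0.0027, and adjusted p = 0.65 with an estimated correlation). Immediate early genes had 3 of 17 lower, with Egr3 at -2.89 (SE 0.3, edgeR adjusted p = 4.1e-05) and Egr1 at -0.9 (median -0.15, camera adjusted p = 0.038, and adjusted p = 0.65 with an estimated correlation). Oxidative phosphorylation genes had 18 of 35 higher and 0 lower (median 0.55, camera adjusted p = 2.6e-10) and ribosomal protein genes 14 of 48 higher and 0 lower (median 0.39, camera adjusted p = 3.8e-09), each at adjusted p = 0.65 with an estimated correlation. In all 15 of 36 lists passed camera and 0 with an estimated correlation.

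The count of 2650 genes was 1394 without replicate 2 of the Q22 double knock-in, 797 without its replicate 3 and 719 without replicate 1 of the Q33 double knock-in, and 73 with the mitochondrial ribosomal RNA covariate. Library totals gave 295 genes higher and 3625 lower. Under library totals 9 oxidative phosphorylation genes, 2 ribosomal protein genes and 3 motor neuron markers were higher, 6 pan-neuronal genes higher and 4 lower, and 7 dorsal horn, 9 axon injury, 8 reactive astrocyte and 4 immediate early genes lower. The pan-neuronal list lost its call without replicate 2 of the Q22 double knock-in (mean log2 fold change 0.22 in place of 0.28), and the immediate early list without replicate 1 of the Q22 double knock-in (mean -0.41 in place of -0.42) or replicate 1 or 3 of the Q33 double knock-in (-0.34 and -0.43).

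Against TDP-43 alone, the comparison asked what ATXN2 with the longer tract added. Lmx1b fell from 20.8 ± 6.9 to 3.41 ± 2.32 CPM (SD, n = 3). Aplnr (log2 fold change -4.38, SE 0.58, edgeR adjusted p = 0.00051), Car12 (-3.92, SE 0.41, 9e-05) and Egr3 (-2.39, SE 0.3, 0.00037) fell, and Snap25 (0.74) and Esrrg (0.71) rose. The inducible heat shock gene Hspa1b fell by 3.33 (SE 0.63, edgeR adjusted p = 0.0038) from a TDP-43 level of 11.3 ± 13.3 CPM, for which the libraries gave 4.1, 26.62 and 3.13 CPM. edgeR called 1235 genes higher and 1375 lower, 45 and 424 of them at least 2-fold.

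Of the dorsal horn markers 6 of 12 fell and 1 rose (median -0.58, camera adjusted p = 0.0044, and adjusted p = 0.58 with an estimated correlation). Myelin genes had 6 of 19 lower, with Myrf at -0.54 (median -0.38, camera adjusted p = 7.7e-05), reactive astrocyte genes 7 of 18 lower and 1 higher (median -0.5, camera adjusted p = 0.0013) and precursor markers 5 of 12 lower and 1 higher (median -0.2, camera adjusted p = 0.024), each at adjusted p = 0.58 with an estimated correlation. Homeostatic microglia markers had 3 of 16 lower, with Sall1 at -0.69 and Csf1r at -0.64 (median -0.39, camera adjusted p = 0.0013, and adjusted p = 0.61 with an estimated correlation). Oxidative phosphorylation genes had 15 of 35 higher, with Uqcrc2 at 0.58 (median 0.5, camera adjusted p = 8.5e-10), and ribosomal protein genes 9 of 48 higher, with Rpl15 at 0.53 (median 0.36, camera adjusted p = 3.9e-09), each at adjusted p = 0.58 with an estimated correlation. Under library totals 10 oxidative phosphorylation genes and 1 ribosomal protein gene were higher, and 6 dorsal horn, 17 myelin, 7 reactive astrocyte, 6 precursor and 9 homeostatic microglia genes lower. In all 14 of 36 lists passed camera and 0 with an estimated correlation. The count of 2610 genes was 1176 without TDP-43 replicate 1, 744 without TDP-43 replicate 3, 552 without replicate 1 of the Q33 double knock-in, 256 with only these 6 libraries in the fit, 391 with the Hox covariate and 3 with the mitochondrial ribosomal RNA covariate. Library totals gave 256 genes higher and 3828 lower.

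A comparison of the Q33 double knock-in with Q33 was added after the data were seen. Lmx1b was 3.41 ± 2.32 against 15.2 ± 2.97 CPM (log2 fold change -2.17, SE 0.33, edgeR adjusted p = 0.0057), and Car12 (-2.71, SE 0.43, 0.0073), Ebf2 (-2.69, SE 0.42, 0.0068) and Aplnr (-3.39, SE 0.6, 0.011) were also lower, with no overlap between the libraries, which the rule for the largest changes requires. edgeR called 44 genes higher and 140 lower, DESeq2 539 and 494 (1033 in all) and limma-voom 408 and 361. The balance thus depends on the method. Dorsal horn markers had 2 of 12 lower (median -0.71, camera adjusted p = 7.9e-05, and adjusted p = 0.33 with an estimated correlation), and 4 lower under library totals. Motor neuron markers and pan-neuronal genes had medians of 0 and -0.01. In all 10 of 36 lists passed camera against 0 with an estimated correlation. The 184 calls became 21, 31 and 102 without Q33 replicates 1, 2 and 3, 7 without replicate 1 and 395 without replicate 3 of the Q33 double knock-in, and 0 with the mitochondrial ribosomal RNA covariate. All 4 genes named here lost their calls without replicate 1 of the Q33 double knock-in, and Aplnr also without Q33 replicate 1.

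The comparisons of the Q33 double knock-in shared many calls. Against NTg and against the Q22 double knock-in, 1786 genes were called in both, against NTg and TDP-43 1683, and against both TDP-43 groups 1833, all with the same sign. Independent lists of these sizes would share 320, 315 and 335. The covariances of the log2 fold changes were 0.237, 0.237 and 0.23, against 0.059, 0.06 and 0.061 in simulated data where only the libraries of the Q33 double knock-in were shared and no gene differed. Part of the overlap may come from those shared libraries.

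The planned interactions asked whether the ATXN2 knock-in changed the cord differently with and without human TDP-43. For the Q33 tract edgeR called 0 genes, with 2674 at an unadjusted p under 0.05 (1032 by chance) and a smallest adjusted p of 0.12, while DESeq2 called 118 and limma-voom 9. For the Q22 tract edgeR called 0, with 828 at an unadjusted p under 0.05 and a smallest adjusted p of 0.44, DESeq2 2 and limma-voom 0. The Q33 count was 3 without NTg replicate 1, 48 without TDP-43 replicate 2 and 2 without replicate 3 of the Q33 double knock-in. In the Q33 interaction 11 lists passed camera, with medians of -0.43 for dorsal horn markers, -0.27 for myelin genes, -0.28 for precursor markers and -2.66 for erythroid genes, and in the Q22 interaction 6 did, with -0.43 for heat shock genes and -0.21 for unfolded protein response genes. With an estimated correlation 0 lists passed, at adjusted p = 0.9 and adjusted p = 0.85. The dorsal horn list of the Q33 interaction lost its call without Q33 replicate 2 (mean log2 difference -0.5 in place of -0.68) or replicate 2 of the Q33 double knock-in (-0.54).

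A further contrast, added after the data were seen, asked whether the difference between the 33 and 22 glutamine forms was itself different with human TDP-43. Egr3 (log2 difference -2.62, SE 0.4, edgeR adjusted p = 0.0092), Lmx1b (-2.55, SE 0.44, 0.023), Car12 (-3.13, SE 0.54, 0.023) and Aplnr (-4.15, SE 0.75, 0.026) were among 67 genes with a more negative difference in the double knock-ins, and Esrrg (0.82, SE 0.17, 0.041) was among 4 with a more positive one. Dorsal horn markers had a median of -1.07 with 2 of 12 called (camera adjusted p = 0.00041, and adjusted p = 0.52 with an estimated correlation). Library totals gave 3 and 160. DESeq2 was near balance, with 291 more positive and 303 more negative (594 in all), as were limma-voom with 219 and 221 (440 in all) and edgeR with no filter (378 and 460). Other edgeR fits stayed one-sided: 4 and 68 with median-of-ratios scaling, 6 and 79 with the filter of 1 CPM and 2 and 37 with the sex covariate. With only the groups compared the counts were 36 and 132. The 71 edgeR calls became 10, 12 and 35 without Q22 replicates 1, 2 and 3, 9 and 9 without Q33 replicates 1 and 2, 251, 12 and 9 without replicates 1, 2 and 3 of the Q22 double knock-in, and 6 and 113 without replicates 1 and 3 of the Q33 double knock-in. They became 39 with sex and 0 with mitochondrial ribosomal RNA as a covariate.

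Each single knock-in was compared with NTg for its own effect. In TDP-43 cords the inducible heat shock genes had the smallest p-values: Hspa1b was 11.3 ± 13.3 against 0.648 ± 0.172 CPM (log2 fold change 4.11, SE 0.67, edgeR adjusted p = 0.093; chromosome 17, 34956436 to 34959238, ENSMUSG00000090877.3), Hspa1a 14 ± 14.4 against 2.39 ± 0.43 CPM and Dnajb1 1.12 higher on the log2 scale (SD, n = 3). Ahsa2, a cochaperone gene, was 0.73 higher (SE 0.12, edgeR adjusted p = 0.093). None of them passed. edgeR called 0 genes, with 873 at an unadjusted p under 0.05 (1032 by chance), DESeq2 6 and limma-voom 0. Heat shock genes (median 0.37, 0 of 15 called and 4 higher adjusted over the list alone, camera adjusted p = 7.1e-08, and adjusted p = 0.97 with an estimated correlation) and unfolded protein response genes (median 0.25, 0 of 22 called and 6 higher adjusted over the list alone, camera adjusted p = 7.1e-08, and adjusted p = 0.79 with an estimated correlation) were 2 of 6 lists that passed camera. Hspa1b and Hspa1a are near-identical copies, so the reads of each are uncertain. edgeR called 3 genes without TDP-43 replicate 1 and 3 without TDP-43 replicate 3. Without TDP-43 replicate 2, the library with 26.62 CPM, the Hspa1b estimate was 2.45 (edgeR adjusted p = 0.3, within a range from far under 1e-04 with no filter to 1 over all alternatives).

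In Q33 cords the clock output gene Dbp was 16 ± 2.49 against 29.1 ± 0.759 CPM in NTg (log2 fold change -0.87, SE 0.15, edgeR adjusted p = 0.25; SD, n = 3; chromosome 7, 45705088 to 45710203, ENSMUSG00000059824.12), and Car12 was 1.46 lower on the log2 scale. edgeR called 0 genes, with 1502 at an unadjusted p under 0.05 (1032 by chance), DESeq2 2 and limma-voom 1. Of 36 lists 15 passed camera, including motor neuron markers (median 0.66, adjusted p = 1.2e-06), oxidative phosphorylation genes (0.27, 1.2e-06), reactive astrocyte genes (-0.28, 0.0043, with 3 lower adjusted over the list alone), erythroid genes (1.59, 4.3e-05, with 5 higher adjusted over the list alone) and skeletal muscle genes (2.05, 0.0013). With an estimated correlation 0 passed, at adjusted p between 0.52 and 0.55. The reactive astrocyte list lost its call without Q33 replicate 2 (mean log2 fold change -0.36 in place of -0.43).

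In Q22 cords Gabra2, the gene of a GABA-A receptor subunit, was 140 ± 12.3 against 82.6 ± 3.78 CPM in NTg (log2 fold change 0.76, SE 0.14, edgeR adjusted p = 0.75; SD, n = 3). edgeR called 0 genes, with 873 at an unadjusted p under 0.05 (1032 by chance), and DESeq2 and limma-voom 1 each. Of 36 lists 12 passed camera, including oxidative phosphorylation genes (median 0.25, adjusted p = 1.5e-05), skeletal muscle genes (2.41, 0.00034, with Myl1 at 3.44), pericyte markers (0.24, 0.0081) and antigen presentation genes (0.44, 0.0081). With an estimated correlation 0 passed, at adjusted p = 0.78 or above. The number of lists was 5 without NTg replicate 1, 7 without NTg replicate 2 and 6 without Q22 replicate 2, and the skeletal muscle list lost its call without Q22 replicate 3 (mean log2 fold change 0.75 in place of 2.3). The pericyte list lost its call without NTg replicate 2 (mean 0.24 in place of 0.36) or Q22 replicate 2 (0.26), and the antigen presentation list without NTg replicate 1 (mean 0.38 in place of 0.4) or Q22 replicate 2 (0.25).

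Q33 was compared with Q22 for the effect of tract length without human TDP-43. Dbp was 16 ± 2.49 against 30.4 ± 0.843 CPM (log2 fold change -0.93, SE 0.15, edgeR adjusted p = 0.11; SD, n = 3) and did not pass. edgeR called 0 genes, with 442 at an unadjusted p under 0.05 (1032 by chance), and DESeq2 and limma-voom 1 each. The circadian clock genes had 0 of 18 called and 2 higher and 4 lower adjusted over the list alone, with a median of -0.12 (camera adjusted p = 0.0028, and adjusted p = 0.075 with an estimated correlation). Motor neuron markers had a median of 0.45 (camera adjusted p = 0.00027, and adjusted p = 0.87 with an estimated correlation), lost without Q33 replicate 3 (mean 0.19 in place of 0.43). The number of lists that passed camera was 11, and 4 without Q22 replicate 2 or Q33 replicate 3.

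The Q22 double knock-in differed from NTg in 2 genes. Gabra2 rose from 82.6 ± 3.78 to 168 ± 29.2 CPM (log2 fold change 1.03, SE 0.14, edgeR adjusted p = 0.018; SD, n = 3; chromosome 5, 70957597 to 71095849, ENSMUSG00000000560.9), higher in 3 of 3 libraries than in any NTg library. Gm43041, a gene model without a known role, fell by 1.14 on the log2 scale (SE 0.18, edgeR adjusted p = 0.046). There were 474 genes at an unadjusted p under 0.05 (1032 by chance), and DESeq2 called 2 and limma-voom 1. Immediate early genes (median 0.2, camera adjusted p = 9.4e-07, and adjusted p = 0.66 with an estimated correlation) and pericyte markers (0.47, 5.9e-05, and adjusted p = 0.78 with an estimated correlation) were 2 of 4 lists that passed camera. edgeR called 0 genes without NTg replicate 1, 2 or 3 or replicate 3 of the Q22 double knock-in, and 1 gene without its replicate 1 or 2. The Gabra2 adjusted p was 0.09, 0.14, 0.22 and 0.11 in the first 4 of these fits. The number of lists was 11 without replicate 2 and 7 without replicate 3 of the Q22 double knock-in.

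**Figure D5:**
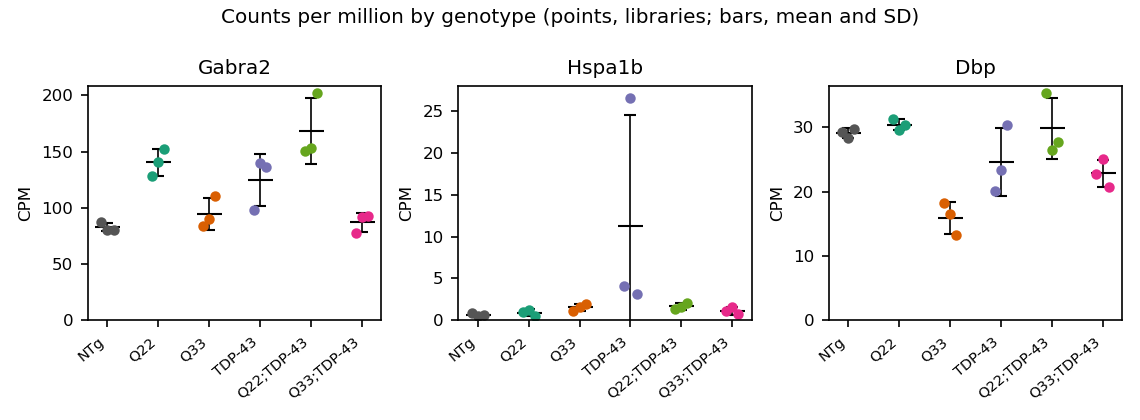
CPM of Gabra2, Hspa1b and Dbp by genotype, with points for libraries and bars for the mean and SD of 3 libraries. Gabra2 averaged 168 CPM in the Q22 double knock-in against 82.6 in NTg, Hspa1b reached 26.62 CPM in 1 TDP-43 library, and Dbp averaged 16 CPM in Q33 against 29.1 in NTg.

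Between the Q22 double knock-in and TDP-43 edgeR called 0 genes, with 497 at an unadjusted p under 0.05 (1032 by chance), and DESeq2 and limma-voom called 0. Hspa1b had a log2 fold change of -2.81 (SE 0.6, edgeR adjusted p = 1). Unfolded protein response genes (median -0.21, camera adjusted p = 7.2e-08), heat shock genes (-0.22, 1.9e-07) and myelin genes (-0.18, 4e-05) were 3 of 6 lists that passed camera, each at adjusted p = 0.56 with an estimated correlation. The heat shock list lost its call without TDP-43 replicate 2 (mean log2 fold change -0.17 in place of -0.55) and the myelin list without replicate 1 of the Q22 double knock-in (mean -0.07 in place of -0.17). The number of lists was 12 and 10 without TDP-43 replicates 2 and 3 and 3 and 13 without replicates 1 and 2 of the Q22 double knock-in, and edgeR called 1 gene without replicate 3 of the Q22 double knock-in.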

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

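The tract length contrast behind this part, and so all tests named in it, were chosen after the result was seen, except the count of other splits, which was set before that count was known. The step from 22 to 33 glutamines differed with and without human TDP-43 for 71 genes (edgeR adjusted p under 0.05). The genes named below were first named in the comparison of both double knock-ins, and were kept if they passed this contrast. That comparison is part of the contrast and uses the same libraries, so their passing is not independent support. Of 30 splits of the libraries, 1, the real one, gave as many genes, and the highest of the others gave 1. The contrast was added after the data were seen, and the other splits mix groups that differ, which can raise the spread and lower their counts, so these splits decide nothing about chance. The count was 6 without replicate 1 of the Q33 double knock-in, and 0 with the share of mitochondrial ribosomal RNA as a covariate.

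Among these genes the immediate early gene Egr3 had a log2 difference of -2.62 (SE 0.4, edgeR adjusted p = 0.0092). Lmx1b of dorsal excitatory interneurons had -2.55 (SE 0.44, adjusted p = 0.023) and the somatostatin gene Sst -1.6 (SE 0.33, adjusted p = 0.041). The transcription factor gene Ebf2 had -3.25 (SE 0.56, adjusted p = 0.023), Car12 -3.13 (SE 0.54, adjusted p = 0.023), Aplnr -4.15 (SE 0.75, adjusted p = 0.026), the neuromedin U receptor gene Nmur2 -3.78 (SE 0.78, adjusted p = 0.041) and Cd44 -1.89 (SE 0.38, adjusted p = 0.041). Esrrg, a nuclear receptor gene of gamma motor neurons, had 0.82 (SE 0.17, adjusted p = 0.041).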

How the results depend on the processing

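The covariates, library totals, the fit without mitochondrial genes and 2 of the contrasts were chosen after the data were seen, and unless a reason is given the cause was not tested. No paired analysis was possible because replicate numbers only follow accession order. Of 85 named genes that passed in the Q33 double knock-in against NTg, 50 passed in every fit without 1 library, 84 with DESeq2 and 53 with the Hox covariate, and 4, among them Aplnr, Car12 and Ebf2, with mitochondrial ribosomal RNA as a covariate and in every alternative. Against the Q22 double knock-in 51 of 88 passed in every fit without 1 library and 10 in every alternative, and against TDP-43 44 and 1 of 84. Counts within 1.5 times the main value are not repeated.

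DESeq2 called 1 gene for Q22, 2 for Q33 and 6 for TDP-43 against NTg, 1 for Q33 against Q22, 2 and 118 for the Q22 and Q33 interactions, 1033 for the Q33 double knock-in against Q33 and 594 for the tract length contrast. limma-voom called 1, 1 and 1 for Q22, Q33 and the Q22 double knock-in against NTg, 1 for Q33 against Q22, 9 for the Q33 interaction, 769 for the Q33 double knock-in against Q33 and 440 for the tract length contrast. With no filter the counts were 238, 408, 84 and 39 for Q22, Q33, TDP-43 and the Q22 double knock-in against NTg, 70 for Q33 against Q22, 49 for the Q22 double knock-in against TDP-43, 193 and 533 for the Q22 and Q33 interactions, 1147 for the Q33 double knock-in against Q33 and 838 for the tract length contrast, nearly all among genes that the main filter keeps (233 of 238 for Q22). The smallest edgeR adjusted p was then 3.6e-273 for Q33 and 3.4e-258 for TDP-43 against NTg, in place of 0.25 and 0.093. Values so small are not credible for groups of this size. The counts without a filter are therefore no evidence that the main filter hides real changes. With only the groups compared, the counts were 6 for Q22 and 0 for the Q22 double knock-in against NTg, 1534, 1383, 256 and 96 for the Q33 double knock-in against NTg, the Q22 double knock-in, TDP-43 and Q33, and 168 for the tract length contrast. The 2 calls of the Q22 double knock-in against NTg became 1 with median-of-ratios scaling (RLE), sex, Hox, mitochondrial ribosomal RNA or without mitochondrial genes, and 0 with library totals. Sex as a covariate gave 39 for the tract length contrast. The Hox covariate gave 646 and 391 for the Q33 double knock-in against NTg and TDP-43. Mitochondrial ribosomal RNA as a covariate gave 28, 73, 3 and 0 for the Q33 double knock-in against NTg, the Q22 double knock-in, TDP-43 and Q33, and 0 for the tract length contrast. Library totals gave 4146, 4084 and 396 against NTg, TDP-43 and Q33 and 163 for the tract length contrast, with 206 higher and 3940 lower against NTg, 295 and 3625 against the Q22 double knock-in, 256 and 3828 against TDP-43, 12 and 384 against Q33 and 3 and 160 in the contrast. Tardbp then passed in the Q33 double knock-in against NTg at -0.28 in place of -0.04, where the median of all genes was -0.253 in place of -0.012. The 1 call shared among comparisons with NTg became 4 with DESeq2.

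Without 1 library, counts ranged from 0 to 0 for Q22 and Q33 against NTg, Q33 against Q22 and the Q22 interaction, 0 to 3 for TDP-43 and 0 to 1 for the Q22 double knock-in against NTg, 0 to 1 for the latter against TDP-43, 602 to 3048 for the Q33 double knock-in against NTg, 719 to 3152 against the Q22 double knock-in, 552 to 3431 against TDP-43 and 7 to 395 against Q33, 0 to 48 for the Q33 interaction and 6 to 251 for the tract length contrast. With an estimated correlation 0 lists passed in all 13 comparisons. With fry, 9, 7, 8 and 2 lists passed for the Q33 double knock-in against NTg, the Q22 double knock-in, TDP-43 and Q33, 1 each for Q33 against Q22 and the tract length contrast, and 0 in the other 7. Numbers of lists that passed camera without 1 library ranged from 5 to 10 for Q22, 13 to 19 for Q33, 3 to 9 for TDP-43, 4 to 11 for the Q22 and 13 to 19 for the Q33 double knock-in against NTg, 4 to 12 for Q33 against Q22, 10 to 16 for the Q33 against the Q22 double knock-in, 3 to 13 and 11 to 16 for both against TDP-43, 9 to 14 for the Q33 double knock-in against Q33, 3 to 9 and 8 to 12 for the Q22 and Q33 interactions and 6 to 13 for the tract length contrast. The mean log2 fold change of erythroid genes in the Q22 double knock-in against TDP-43 was -1.2 with all libraries, 0.06 without TDP-43 replicate 2, and at its lowest -1.55, without TDP-43 replicate 1. That of motor neuron markers in the tract length contrast was 0.39, -0.08 without replicate 2 of the Q33 double knock-in, and at its highest 0.65, without replicate 1 of the Q22 double knock-in. Depth limits genes near 0.19 CPM, the highest floor.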

Other observations

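The covariate and scaling alternatives, the lists of dorsal and ventral neuron genes, the readings of strain markers, the tests of the dorsal horn and Gabra2 patterns, the mitochondrial ribosomal RNA test of the ribosomal and oxidative phosphorylation genes, and the counts of splits for comparisons with 0 calls were chosen after the results were seen. Dorsal inhibitory neuron genes were lower in the Q33 double knock-in, like the excitatory ones: 6 of 12 fell against NTg and 0 rose (median log2 fold change -0.7), including Gbx1 (-2.22, SE 0.26, edgeR adjusted p = 1e-04), the dynorphin gene Pdyn (-1.84, SE 0.23, 0.00013), Lbx1 (-1.01) and Npy (-1.61, a call lost without replicate 1 of the Q33 double knock-in at -1.28 and adjusted p = 0.073). Ventral cord neuron genes had 1 of 11 higher, En1 (1.64, SE 0.29, edgeR adjusted p = 0.0024), 0 lower and a median of 0.6. Against TDP-43 the medians were -0.66 and 0.62, and against the Q22 double knock-in -1.09 and 0.63. Of these genes Npy and Gal of the dorsal list and Chat, Slc5a7, Slc18a3, Mnx1 and Isl1 of the ventral list also stand in other lists.

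The strain marker Wdfy1, which differs between C57BL/6 substrains, lay between 25.65 and 28.7 CPM in 8 libraries (2 of Q22, 2 of TDP-43, 1 of the Q22 double knock-in and 3 of the Q33 double knock-in) and between 11.96 and 17.75 CPM in the other 10. Q22 replicate 2 had Xist at 99.9 CPM together with 201 CPM of Y-linked reads, against Xist of 4.83 and 5.63 CPM in the other Q22 libraries.

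Other splits of the same libraries were counted for each comparison. Splits of 3 against 3 libraries are too few for a share under 0.05. Against NTg the Q33 double knock-in had 2491 calls and the highest of the other splits 0 (1 of 10 splits gave as many), and the Q22 double knock-in had 2 calls against 0 (1 of 10). Against the Q22 double knock-in, TDP-43 and Q33, the Q33 double knock-in had 2650, 2610 and 184 calls and the highest other splits 0, 1 and 0 (1 of 10 each). The comparisons of Q22, Q33 and TDP-43 with NTg, of Q33 with Q22 and of the Q22 double knock-in with TDP-43 had 0 calls, which 10 of 10 splits equalled, and the highest other split was 2 for TDP-43 and 0 for the rest. Both interactions had 0 calls, equalled by 30 of 30 splits, and the highest other split gave 1 for the Q33 and 537 for the Q22 interaction. Any split equals a count of 0, so these counts say nothing about chance. The split with 537 calls points to some structure of the samples, which was not identified or tested.

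Dorsal horn markers were lower in the Q33 double knock-in (mean log2 CPM difference from NTg -1.34). Slopes were taken within the groups other than the Q33 double knock-in and applied to its difference from NTg. The slope on the Hox score predicts 0.07 ± 0.09 (SE), and the slope on mitochondrial ribosomal RNA 0.05 ± 0.19. Neither trend, if it holds in this group, accounts for the fall. The group averaged 26.1% mitochondrial ribosomal RNA and the libraries behind the slope reached 23.4%, so the latter prediction goes beyond their range. The Hox score covers only the lumbar and sacral levels. With mitochondrial ribosomal RNA as a covariate 1 of 12 markers passed in place of 7. The mean log2 fold change was -1.2 (mean SE 0.45) in place of -1.23 (0.32), so calls were lost with the wider error and not with the size. With the Hox covariate 5 passed, at a mean of -1.25 (0.36). Dorsal inhibitory genes, with a median of -0.7 and 6 of 12 called, were lower too. The fall was not uniform: Nxph1 (0.07), Klhl14 (0.18) and Rorb (-0.16) were near unchanged against NTg and did not pass. A fall in many of these genes would be seen with less dorsal tissue in these samples or with fewer dorsal neurons of any class. A difference in dissection and a loss of neurons in this genotype both stay open.

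Ribosomal protein and oxidative phosphorylation genes were higher in the same cords (mean log2 CPM difference 0.49). Slopes were again taken within the groups other than the Q33 double knock-in. The slope on the Hox score predicts -0.01 ± 0.09 (SE), so the trend with that score does not account for the size of the rise. The score holds only genes of the lumbar and sacral levels, so it cannot decide on differences between other levels of the cord. With the Hox covariate 3 and 4 genes passed in place of 15 and 22, at means of 0.43 (mean SE 0.22) and 0.52 (0.25), with wider errors. The 10000 random lists matched on summed exon length had upper bounds of 0.14 for the ribosomal list and 0.16 for the oxidative phosphorylation list, against means of 0.43 and 0.59. Summed exon length therefore does not account for the rise either. The random lists were not matched on transcript length or expression level, so they cannot decide on a bias from those. The slope on mitochondrial ribosomal RNA predicts 0.2 ± 0.17 of the 0.49, and with it as a covariate the means were 0.09 (mean SE 0.25, in place of 0.43 and 0.19) and 0.36 (0.3, in place of 0.59 and 0.21), with 0 calls, and under library totals 3 of 48 ribosomal protein genes and 8 of 35 oxidative phosphorylation genes were higher, in place of 15 and 22. RNA composition or quality and the genotype cannot be told apart for these genes, because the share of mitochondrial ribosomal RNA moves with the group. A biological effect of the genotype on them stays open and was not tested separately.

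Gabra2 was higher in the Q22 double knock-in (168 ± 29.2 CPM) than in NTg (82.6 ± 3.78). With sex as a covariate it still passed (edgeR adjusted p = 0.031, within a range from far under 1e-04 with no filter to 0.22 over its alternatives), which argues against sex balance as the whole cause. Gabra2 carries a known variant that lowers its level in the C57BL/6J substrain, so a different strain background near the gene may be the source. Of the other strain markers 0 were called in this comparison, though 2 of the 8 estimates lay more than 3 SEs from 0, each at an edgeR adjusted p of 1, which decides neither way, and strain and genotype cannot be told apart here because the labels give no substrain. An effect of the knock-in also stays open.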
